A study of Mus musculus with 6 samples.

How the data were processed

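RNA was measured in 6 tumours of the mouse fibrosarcoma line UV2237M, 3 untreated and 3 given gold nanoclusters with near-infrared irradiation. Samples were assigned to groups from their titles, and the treatment from the labels. Per the labels, total RNA was taken with Trizol and libraries were made with a kit that keeps the strand of the RNA. Per the submitters' processing notes, the tools include TopHat (version not given) and the genome build mm10. The counting program, its strand setting and the gene annotation are not given in the sources used here. Antisense and overlapping genes can therefore share counts.

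The deposited values are whole-number counts per gene symbol, 1 table per sample with the same 23183 symbols in each, and they were used without rescaling. The deposited counts sum to between 4680295 and 8019294 per library, and the 10 most abundant genes held 6.00% to 7.96% of them. At these depths a gene with few counts has a wide counting error, so genes were filtered. With edgeR 4.0.16 (R 4.3.3), filterByExpr at its smallest count of 10 kept 12517 genes, and 4966 of the others had no count in any library. Counts were scaled with TMM, whose factors lay between 0.96 and 1.02, and groups were compared with the quasi-likelihood test (glmQLFit and glmQLFTest), 2-sided, with Benjamini-Hochberg adjustment over the tested genes. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1, so none was used. CPM were computed here with the TMM library sizes, and their mean and SD are over 3 libraries. The SE of a log2 fold change is its size divided by the root of the F statistic.

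Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 3, an inter-gene correlation of 0.01 and adjustment over the 42 lists with at least 5 tested members. The 31 pathway and 18 cell type lists hold 735 genes, 712 of them in the tables and 591 tested, with 13 genes in more than 1 list. The lists, the tests, most alternatives and the rule for named genes were written before the data were examined. The rule passes over gene models without a name, pseudogenes and small RNAs. It names the 8 genes per direction with the largest fold change among those past the threshold, without overlap of the groups and with at least 5 CPM. Where none passes, it names the 4 with the smallest unadjusted p per direction, given as values, which was the case here. For each list described in more than a count it names the 2 members with the smallest p and up to 2 of the other direction. It also names 12 genes whatever their values, Hspa1a, Hspa1b, Dnajb1, Abcb1a, Abcb1b, Abcc1, Mt1, Mt2, Hmox1, Cdkn1a, Mki67 and Vegfa. Of the genes the rule names, 2 list members are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

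No pair of libraries agreed within sampling noise. The chi-square statistic per gene, over genes with at least 20 counts in the pair, was 5.64 or more, where noise alone gives about 1. GC content and length were taken from the longest transcript of each gene in GENCODE M21. Of the symbols, 22148 matched by name and 649 through a RefSeq synonym, and 99.4% of the tested genes had a value. For 1 alternative a loess trend with GC content and log10 length (span 0.3) was removed from each library. Coordinates are those of GENCODE M21, on mm10.

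The steps were tested on simulated counts drawn from the real means, library sizes and dispersions of 12517 genes. With the spread of the 6 libraries, edgeR recovered 3 of 100 genes changed by 2-fold and 54 of 100 changed by 4-fold, with 6 false calls. With the spread found without untreated 2, still drawn for 6 libraries, it recovered 71 of 100 and 93 of 100, with 13 false calls. The real fit without untreated 2 has 5 libraries, so these shares do not apply to it. In both runs all libraries had the same spread, which does not mimic a single library that stands apart. Camera with the preset correlation found 10 of 10 lists of 20 independent genes raised by 0.5 log2 and called 0 of 32 unchanged lists, and with an estimated correlation it found 0 of 10. Real genes of a list are correlated, which the simulated ones were not. The GC correction brought a simulated correlation with GC content from -0.766 to -0.00075.

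The alternatives chosen in advance were DESeq2 size factors or the upper quartile in place of TMM, DESeq2 (version 1.42.0), limma-voom, no filter, a filter at a mean of 5 CPM, leaving out each library in turn, the replicate number as a block, and an estimated inter-gene correlation. Chosen after seeing the data were the GC and length correction, limma-voom with sample quality weights, DESeq2 on the 5 libraries other than untreated 2, and fry, which tests whether a list's genes move one way and does not compare them with other genes. A pseudocount and limma without a trend had been planned for normalised values only and did not apply to counts.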

Results

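RNA was sequenced from 6 tumours of UV2237M, a mouse fibrosarcoma cell line (a tumour of connective tissue cells). In 3 tumours, called untreated here, no treatment was given. The other 3, called treated, received gold nanoclusters (GNC), particles of gold atoms that turn absorbed light into heat, on day 1 and day 7 together with near-infrared (NIR) irradiation. The deposited values were whole-number counts for 23183 gene symbols. The total count was 6564725, 4680295 and 8019294 in untreated 1, 2 and 3 and 5696774, 7287163 and 7915087 in treated 1, 2 and 3. Between 15016 and 16384 genes had at least 1 count in a library. The labels do not say that the tumours came from separate animals, so the p-values for single genes measure the spread between these samples.

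Untreated 2 stood apart from the other 5 libraries. Its mean distance to them was 1.22 on the scale of log2 CPM, counts scaled to library size,, against 0.611 to 0.729 for the others, and the first principal component, with 67.4% of the variance, separated it from the rest. Genes with a GC-rich longest transcript were low in it. With the tested genes parted into 5 equal bins by GC content, the median gene of the lowest bin lay 0.76 log2 above the mean of the other libraries and that of the highest bin lay at -0.76. *Col1a1*, which codes for the main chain of type I collagen and was named after its values were seen, had 59.4 CPM in untreated 2 and 1975 to 4255 CPM in the other 5. The common biological coefficient of variation was 33.7% over the 6 libraries and 17.3% without untreated 2.

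**Figure D1:**
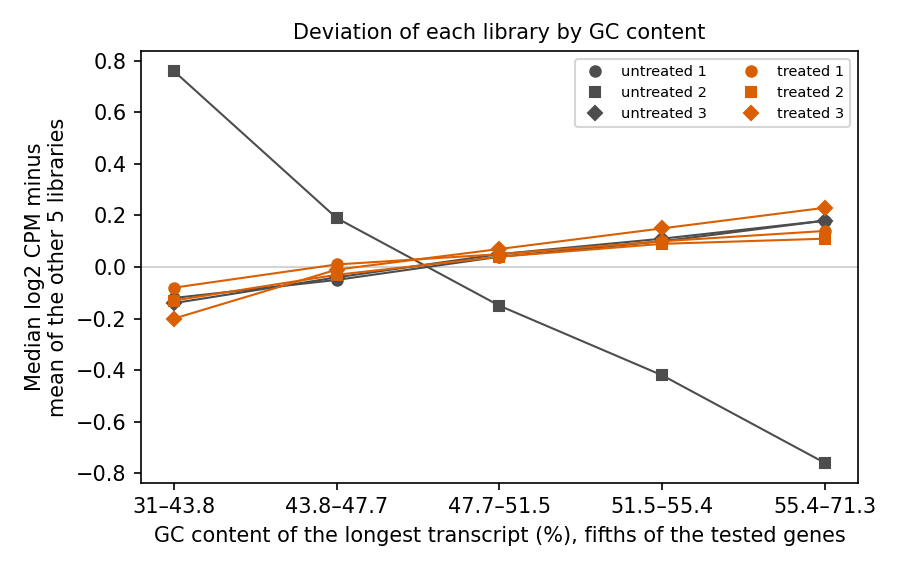
Median deviation of each library from the mean of the other 5 (log2 CPM, vertical axis) in 5 equal bins of the tested genes by GC content in percent (horizontal axis), with the 3 untreated libraries in grey and the 3 treated in orange. Untreated 2 runs from 0.76 to -0.76, and the other 5 stay between -0.2 and 0.23.

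The comparison of treated with untreated tumours asks how the tumour transcriptome differed after GNC with NIR irradiation, the step named in the series title as guiding a drug combination. The genes with the smallest p among those higher in treated tumours were *Cyr61*, a secreted matrix protein, with 390.5 ± 65.6 CPM against 121.7 ± 14.4 (SD, n = 3), and *Dusp4*, a phosphatase that acts on MAP kinases, with 12.6 ± 3.51 CPM against 1.98 ± 0.629. *Mmp13*, a collagenase, followed with 51.1 ± 17.6 CPM against 11.3 ± 4.14, and *Col24a1*, a fibrillar collagen, with 4.07 ± 1.05 CPM against 0.569 ± 0.234. Among genes lower in treated tumours they were *Mest*, an imprinted gene, with 27.2 ± 6.65 CPM against 89.3 ± 18.7, and *Txnip*, an inhibitor of thioredoxin, with 106.5 ± 24.7 CPM against 364.8 ± 100.5. *Angptl7* had 2.71 ± 0.366 CPM against 8.78 ± 1.62, and *Zmynd15* had 2.97 ± 1.08 CPM against 10.8 ± 0.842. In each of these 8 genes the 3 treated values did not overlap the 3 untreated ones. Genes picked by the smallest p are likely to show this, so it is no further support.

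None of these differences passed the threshold of edgeR's quasi-likelihood test. Of 12517 genes tested, 0 were higher and 0 lower at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.592. At an unadjusted p under 0.05 there were 1023 genes, 416 higher and 607 lower, where 626 would be expected with no difference. The groups did not overlap in 20.8% of the tested genes, against 10% by chance. Both expected values are averages, and counts can stray far from them where genes vary together. Regroupings of the 6 libraries other than the real one gave 42 to 974 genes at an unadjusted p under 0.05. An excess over 626 therefore does not by itself mark an effect of treatment. The share without overlap was not computed for the regroupings. DESeq2 called 15 genes higher and 30 lower, the 8 above among them, and limma-voom called 0. Without untreated 2 edgeR again called 0 genes, with a smallest adjusted p of 0.0549 and 2362 genes at an unadjusted p under 0.05, and DESeq2 called 105 higher and 127 lower. Without untreated 3 edgeR called 4 genes, all lower, *Calm4*, *Hrnr*, *Dmkn* and *Klk7* (named after their values were seen), which are known from epidermis, with log2 fold changes of -9.15, -7.79, -5.56 and -7.38 and an adjusted p of 0.0291. The count at an unadjusted p under 0.05 was 1686 without untreated 3, 574 without treated 1 and 313 without treated 3.

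The log2 fold changes of the extreme genes, with standard errors from edgeR, were 1.68 ± 0.22 for *Cyr61* (chromosome 3, 145646976 to 145649981, mm10), 2.64 ± 0.37 for *Dusp4* (chromosome 8, 34807297 to 34819894), 2.18 ± 0.38 for *Mmp13* (chromosome 9, 7272514 to 7283331) and 2.81 ± 0.48 for *Col24a1* (chromosome 3, 145292472 to 145552011). They were -1.71 ± 0.27 for *Mest* (chromosome 6, 30723547 to 30748465), -1.77 ± 0.29 for *Txnip* (chromosome 3, 96557957 to 96561883), -1.69 ± 0.30 for *Angptl7* (chromosome 4, 148495183 to 148500460) and -1.86 ± 0.33 for *Zmynd15* (chromosome 11, 70459433 to 70466202). The positions are those of the whole genes in the annotation, all protein-coding, and the counts cover each gene as a whole.

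**Figure D2:**
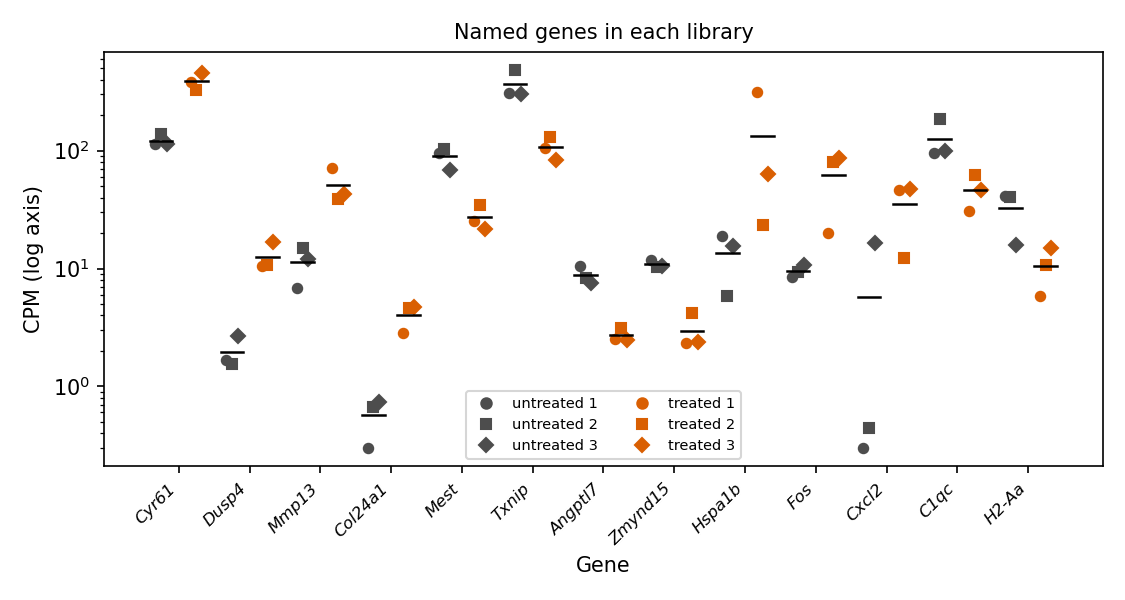
CPM (vertical, log axis) of the 4 genes with the smallest p in each direction and of 5 further genes named in the text, in each of the 3 untreated (grey) and 3 treated (orange) libraries, with group means as horizontal bars. Cyr61 lies at 113 to 138.4 CPM in untreated and 328.9 to 459.5 CPM in treated libraries, while Cxcl2 overlaps between the groups.

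Gene lists fixed before the data were examined were tested against all other genes with camera and a preset inter-gene correlation of 0.01. The p-value of that version rests on the spread between genes and on the preset correlation. It does not measure how far a list as a whole varied between samples. Of 42 lists with at least 5 tested members, 14 rose and 7 fell in treated tumours at an adjusted p under 0.05. With a correlation estimated from the data no list passed, and the lowest adjusted p was 0.499. That version of the test also found 0 of 10 lists raised by 0.5 log2 in simulated data of this size, where the preset version found 10. The simulated genes were independent, which real list members are not, so the simulation cannot decide which version to trust. With the preset correlation, regroupings of the 6 libraries other than the real one called 3 to 15 lists. Without untreated 1, 6 lists rose and 3 fell, and without untreated 2, 15 rose and 4 fell. No member of any list passed edgeR's test over all genes, while DESeq2 called some, named below with their adjusted p. For the 21 lists past the threshold with all 6 libraries, the adjusted p without a library is given where that library decided the call, and the list value where it moved by over 1.5 times. Below, list values are mean log2 CPM differences from the untreated mean with the SD over the 3 treated libraries, followed by the SD over the 3 untreated ones. Treated and untreated libraries overlapped in the values of the called lists for NRF2, S phase, cholesterol synthesis, type I interferon, macrophages, neutrophils, endothelial cells, pericytes and keratinocytes, and not in the other called lists.

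Immediate early genes, which cells switch on within minutes of a stimulus, rose as a list by 1.19 ± 0.54 (untreated SD 0.42), with an adjusted p of 6.1e-07 and an adjusted p of 0.499 with an estimated correlation. The labels do not give the time from the last irradiation to harvest, so what stimulus these genes answered cannot be told. Of 17 tested members 15 were higher and 2 lower, and 8 passed edgeR's test adjusted over the list alone. In 11 of the 17 the treated values lay above each untreated one, as they did in 1322 of the 12517 tested genes. *Fos*, a subunit of the AP-1 transcription factor, had 61.9 ± 36.6 CPM in treated and 9.51 ± 1.11 in untreated tumours (SD, n = 3), and *Dusp1*, another MAP kinase phosphatase, had 58.7 ± 22.9 against 17.1 ± 2.91. Both were among the 8, and DESeq2 called them (adjusted p 0.00143 and 0.00328). *Fosb*, named after its values were seen, had 10.9, 74 and 151.1 CPM in treated 1, 2 and 3 and 6.66, 1.56 and 8.34 in untreated 1, 2 and 3, and DESeq2 called it (0.00626), as it did *Atf3* (0.025), also named after its values were seen. *Egr3* (5.85 ± 3.53 against 9.17 ± 3.99 CPM) and *Jund* (209.7 ± 14.0 against 223.3 ± 65.9 CPM) lay in the other direction, and *Jund* lay above 0 without untreated 2, at a log2 fold change of 0.17. *Egr3* had 1.79 CPM in treated 1 and 8.16 and 7.58 CPM in treated 2 and 3.

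The list of NF-kB targets and inflammatory cytokines rose by 1.66 ± 0.33 (untreated SD 1.00), with an adjusted p of 3.11e-09 and of 0.499 with an estimated correlation. All 19 tested members were higher in treated tumours, 6 of them at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. *Osm*, a cytokine of the interleukin 6 family, had 5.11 ± 2.52 CPM against 1.18 ± 0.688, and *Ccl4*, a chemokine for monocytes, had 4.79 ± 2.23 against 0.606 ± 0.864 (SD, n = 3), with 0, 0.223 and 1.595 CPM in untreated 1, 2 and 3, and its log2 fold change was 2.81 with all libraries and 5.43 without untreated 3. The untreated tumours differed among themselves, with list values of -0.88, -0.22 and 1.10 in untreated 1, 2 and 3 against 1.35 to 2.01 in treated tumours. *Cxcl2* and *Cxcl1*, neutrophil chemokines named after their values were seen, had 0.303, 0.446 and 16.4 CPM and 1.66, 7.36 and 11.5 CPM in untreated 1, 2 and 3 and 46.8, 12.2 and 47.5 CPM and 27, 17.4 and 28.2 CPM in treated 1, 2 and 3, so that *Cxcl2* overlapped between the groups and *Cxcl1* did not. Neutrophil markers rose with an adjusted p of 0.00101 (0.499 with an estimated correlation), by 1.2 ± 0.54 (untreated SD 0.93). All 9 tested markers were higher, and 0 passed over the list alone. *S100a9* had 27.2 ± 14.6 CPM against 6.61 ± 6.34 (0.454, 6.25 and 13.1 in untreated 1, 2 and 3), a log2 fold change of 2.02, or 3.10 without untreated 3, and *Cxcr2*, a chemokine receptor, 8.90 ± 2.35 against 5.08 ± 1.42, and the list value of untreated 3 was 1.01, within the treated range of 0.58 to 1.62.

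Heat shock genes, which code for chaperones, rose by 0.62 ± 0.48 (untreated SD 0.06), with an adjusted p of 0.00409 and of 0.499 with an estimated correlation. Of 20 members 14 were higher and 6 lower, 5 were higher at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. *Hspa1b* (chromosome 17, 34956436 to 34959238), an inducible HSP70 gene, had 315.5, 23.5 and 63.5 CPM in treated 1, 2 and 3 and 18.9, 5.80 and 15.6 in untreated 1, 2 and 3, and DESeq2 called it (adjusted p 0.0324). Its near-identical neighbour *Hspa1a* had 5.71 ± 5.47 CPM against 1.26 ± 1.09, and counting can split reads between the pair, so the value of each is uncertain. *Dnajb1*, a partner of HSP70, had 123.9 ± 112.4 CPM against 58.2 ± 12.9, with 253.7 CPM in treated 1 and a log2 fold change of 1.09, or 0.02 without treated 1, and *Hspd1*, the mitochondrial chaperonin, 614.2 ± 114.3 against 347.8 ± 55.0. *Dnaja1* (233.5 ± 23.8 against 315.0 ± 154.9 CPM) and *Hspa8*, a constitutive HSP70 gene (2759 ± 251.4 against 3508 ± 1215 CPM), lay in the other direction, and *Dnaja1* had a log2 fold change of 0.04 without untreated 2. *Hspa8* too was highest in untreated 2, with 4909 CPM against 2738 and 2878 CPM in untreated 1 and 3. The list's adjusted p was 0.0638 without untreated 1 and 0.0555 without untreated 3, the range over the 6 fits without 1 library being 1.59e-05 to 0.0638. Its value was 0.38 without treated 1, where the adjusted p was 0.0492.

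The NRF2 list of oxidative stress genes rose by 0.35 ± 0.21 (untreated SD 0.16), with an adjusted p of 0.0116 and of 0.499 with an estimated correlation, and with an adjusted p of 0.14 without untreated 1 (range without 1 library 0.000987 to 0.14). Of its 17 members 15 were higher, and 0 passed adjusted over the list alone. *Hmox1*, heme oxygenase 1, had 128.8 ± 36.5 CPM against 77.4 ± 78.3, with 167.7 CPM in untreated 3. The metallothionein list did not pass (adjusted p 0.166), with 168.2 ± 9.90 CPM against 128.0 ± 36.1 for *Mt1* and 206.0 ± 24.1 against 137.2 ± 40.7 for *Mt2*. *Cdkn1a*, a p53 target that slows the cell cycle, had 36.9 ± 15.2 CPM against 18.1 ± 4.19, and the list of p53 targets did not pass (adjusted p 0.217). *Vegfa*, the main angiogenic growth factor, had 73.5 ± 19.0 CPM against 33.5 ± 19.5, and neither the list of angiogenic factors (adjusted p 0.647) nor that of hypoxia genes (adjusted p 0.683) passed.

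Genes of the G2 and M phases rose by 0.52 ± 0.25 (untreated SD 0.29), with an adjusted p of 3.94e-06 and of 0.499 with an estimated correlation. Its value without untreated 1 was 0.34, with an adjusted p of 0.0202 (range without 1 library 2.16e-08 to 0.0202). Of 20 members 19 were higher, 8 at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. *Bub1b*, a spindle checkpoint kinase, had 141.2 ± 21.8 CPM against 88.7 ± 16.1 and *Cdc20*, an activator of mitotic exit, 125.4 ± 29.4 against 69.1 ± 20.7. *Cdk1* was the member with a log2 fold change below 0, at -0.01 ± 0.40 (98.1 ± 22.4 against 99.3 ± 55.1 CPM), which was 0.52 without untreated 2. S phase genes rose by 0.43 ± 0.28 (untreated SD 0.24), with an adjusted p of 0.000255 and of 0.519 with an estimated correlation, and 0.0638 without untreated 1 (range without 1 library 1.85e-07 to 0.0638). Of 19 members 17 were higher, and 0 passed adjusted over the list alone. *Mcm5*, a subunit of the replicative helicase, had 147.8 ± 32.5 CPM against 83.2 ± 13.1 and *Uhrf1* 179.6 ± 41.8 against 104.5 ± 18.0. *Ccne2* (13.02 ± 2.20 against 22.6 ± 19.4 CPM) and *Slbp* (57.3 ± 9.38 against 60.3 ± 19.8 CPM) lay in the other direction with all libraries and at log2 fold changes of 0.18 and 0.22 without untreated 2. *Mki67*, a marker of dividing cells, had 752.8 ± 71.6 CPM against 494.5 ± 152.4.

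Wound healing and coagulation genes rose by 0.57 ± 0.20 (untreated SD 0.44), with an adjusted p of 0.0278 and of 0.522 with an estimated correlation, and 0.275 without untreated 1, where the value was 0.31 (range without 1 library 0.0123 to 0.275). Of 13 tested members 9 were higher, and 3 passed adjusted over the list alone, *Areg* and *Thbd* among them, the latter named after its values were seen. *Areg*, a ligand of the EGF receptor, had 4.61 ± 2.36 CPM against 1.06 ± 0.436. *Plat*, a plasminogen activator (78.6 ± 8.55 against 121.3 ± 20.97 CPM), and *Tfpi*, an inhibitor of coagulation (38.3 ± 4.88 against 69.3 ± 36.0 CPM), lay in the other direction. *Tfpi* had 110.7 CPM in untreated 2 and 51.6 and 45.5 CPM in untreated 1 and 3. DNA repair (adjusted p 0.0278), cholesterol synthesis (0.0278), glycolysis (0.0332) and tubulin genes (0.0478) also rose, by 0.27 ± 0.12, 0.29 ± 0.33, 0.35 ± 0.12 and 0.27 ± 0.14 (untreated SD 0.07, 0.14, 0.28 and 0.10), and the adjusted p with an estimated correlation was 0.499, 0.536, 0.499 and 0.499. In these 4 lists 14 of 18, 13 of 16, 12 of 15 and 10 of 14 tested members were higher, and 0 passed adjusted over the list alone. Their calls were lost without untreated 3 (adjusted p 0.0946, 0.308, 0.077 and 0.247) and without treated 1 (0.121, 0.328, 0.0636 and 0.143). Those of DNA repair, glycolysis and tubulin genes were also lost without untreated 1 (0.238, 0.0745 and 0.193), and that of tubulin genes without treated 3 (0.0738). The lowest adjusted p over these fits was 0.00131, 0.000385, 0.0188 and 0.00259. Glycolysis lay at 0.18 without untreated 2, and cholesterol synthesis at 0.15 without treated 1 and 0.47 without treated 2. Endothelial markers (0.45 ± 0.35, untreated SD 0.65, 13 of 15 higher, adjusted p 0.0278, or 0.539 with an estimated correlation) and pericyte and smooth muscle markers (0.53 ± 0.42, untreated SD 0.44, 8 of 11 higher, adjusted p 0.0254, or 0.522 with an estimated correlation) rose with all 6 libraries but not without untreated 2, where the values were 0.10 and 0.27 and the adjusted p 0.387 and 0.192. Neither passed without treated 3 (0.28 and 0.34, adjusted p 0.184 and 0.108), endothelial markers not without untreated 1 (0.133) and pericyte markers not without treated 2 (0.0537). Without untreated 3 endothelial markers lay at 0.75 (adjusted p 0.00215).

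MHC class II genes, used to present antigen to helper T cells, fell as a list, to -1.02 ± 0.54 (untreated SD 0.42), with an adjusted p of 6.54e-05 and of 0.499 with an estimated correlation. All 8 tested members were lower in treated tumours, and 0 passed adjusted over the list alone. In 4 of the 8 the treated values lay below each untreated one, as they did in 1282 of the 12517 tested genes. *H2-Aa*, a class II chain, had 10.4 ± 4.45 CPM against 32.3 ± 14.3 and *Ciita*, the activator of class II transcription, 1.98 ± 0.965 against 5.76 ± 1.60. The interferon gamma list fell to -0.50 ± 0.28 (untreated SD 0.37), with an adjusted p of 0.000793 and of 0.499 with an estimated correlation, and 0.0771 without untreated 2, where the value was -0.30 (range without 1 library 0.000119 to 0.0771). Of 15 tested members 14 were lower and 0 passed adjusted over the list alone. *Irgm1*, an interferon-induced GTPase, had 37.1 ± 9.62 CPM against 62.2 ± 9.62, and *Cd274*, which codes for PD-L1, lay in the other direction with 10.1 ± 1.95 against 5.91 ± 4.20. *Cd274* had 1.79 CPM in untreated 2 and 5.75 and 10.2 CPM in untreated 1 and 3. MHC class I genes fell to -0.30 ± 0.16 (untreated SD 0.10), with an adjusted p of 0.0254 and of 0.499 with an estimated correlation, 11 of 13 members being lower and 0 passing adjusted over the list alone. *H2-K1* had 136.4 ± 27.2 CPM against 215.5 ± 32.8 and *H2-M3* 6.28 ± 1.44 against 12.0 ± 2.90, while *H2-T23* (10.4 ± 2.88 against 9.01 ± 0.803 CPM) and *Calr* (787.4 ± 49.5 against 722.3 ± 60.4 CPM) lay in the other direction. This call was lost without untreated 1, untreated 3 or treated 1, at an adjusted p of 0.133, 0.0555 and 0.135 (range without 1 library 0.0066 to 0.135). The type I interferon list fell to -0.23 ± 0.16 (untreated SD 0.27) with 15 of 18 members lower, 0 over the list alone and an adjusted p of 0.0465 (0.536 with an estimated correlation). It lay at -0.09 without untreated 2, -0.14 without treated 1 and -0.36 without untreated 3 (adjusted p 0.232, 0.261 and 0.0301), and the adjusted p was 0.133 without untreated 1 (range without 1 library 0.0259 to 0.261). MHC genes form a family of similar sequences, so reads can be shared among them.

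Macrophage markers fell to -0.53 ± 0.45 (untreated SD 0.23), with an adjusted p of 0.00106 and of 0.499 with an estimated correlation. The list values were -1.02, -0.13 and -0.45 in treated 1, 2 and 3, that of treated 2 lying above the -0.26 of untreated 1. Without treated 1 the value was -0.29 and the adjusted p 0.0318 (range without 1 library 5.27e-05 to 0.0318). Of 14 markers 11 were lower and 4 passed adjusted over the list alone, *C1qa*, *C1qb*, *C1qc* and *Csf1r*, of which *C1qa* and *Csf1r* were named after their values were seen. *C1qc* and *C1qb*, subunits of complement C1q made by macrophages, had 46.6 ± 16.0 CPM against 126.3 ± 50.3 and 54.0 ± 15.4 against 132.9 ± 55.8 (SD, n = 3). *Cd14* (61.2 ± 15.0 against 48.3 ± 23.7 CPM) lay in the other direction, and at a log2 fold change of -0.03 without untreated 1. Mast cell and basophil markers fell to -0.64 ± 0.15 (untreated SD 0.19), with an adjusted p of 0.0278 and of 0.499 with an estimated correlation, and 0.142 without untreated 1 (range without 1 library 0.00785 to 0.142). Of 7 tested markers 6 were lower and 4 passed adjusted over the list alone, the mast cell proteases *Mcpt4*, *Cpa3*, *Tpsb2* and *Cma1*, the last 2 named after their values were seen. *Mcpt4* had 2.36 ± 0.861 CPM against 11.2 ± 7.11 and *Cpa3* 3.42 ± 0.747 against 11.2 ± 6.52, while *Hdc*, histidine decarboxylase, had 9.42 ± 3.82 against 3.52 ± 3.46. *Hdc* had 7.48 CPM in untreated 3 and 1.97 and 1.12 CPM in untreated 1 and 2.

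Markers of epidermis also differed between libraries, and were high in untreated 1 and 2 but not in untreated 3. The 14 keratinocyte markers in the tables summed to 1360 and 719 CPM in untreated 1 and 2, to 13.9 CPM in untreated 3 and to 24.1, 15.4 and 79.8 CPM in treated 1, 2 and 3. The list fell to -2.62 ± 1.41 (untreated SD 3.51) with an adjusted p of 0.00994 (0.522 with an estimated correlation), all 7 tested markers being lower and 0 passing adjusted over the list alone. It lay at -1.31 without untreated 1, -1.95 without untreated 2 and -4.61 without untreated 3 (adjusted p 0.162, 0.159 and 1.56e-15, the last the lowest without 1 library). *Krt1* and *Krt10*, keratins of differentiating epidermis, had 262.4 and 278.5 CPM in untreated 1 and 71.2 and 50.9 CPM in untreated 2, and at most 11.2 CPM in the other 4 libraries. *Krt14* and *Krt5*, keratins of basal epidermis named after their values were seen, had 232.8 and 238.2 CPM in untreated 1 and 344.1 and 77.2 CPM in untreated 2. Both had 0 CPM in untreated 3 and in treated 2. They had 8.94 and 4.47 CPM in treated 1 and 24.2 and 18.9 CPM in treated 3. Skeletal muscle markers summed to 1000 CPM in treated 3 and to 26.7 to 311 CPM in the other 5, and the list did not pass (adjusted p 0.85). The 12 tested muscle genes were all higher by edgeR's fold change, with a median of 1.51, while the mean of log2 CPM differed by -0.04 and the test's direction was below 0. Without treated 2 the list lay at 1.02 (adjusted p 0.0359) and without treated 3 at -1.5 (2.81e-07), both with the preset correlation. With an estimated correlation its adjusted p was 0.955 over all 6 libraries, and no such test was run in the fits without a library. *Acta1*, skeletal muscle actin named after its values were seen, had 166.0 CPM in treated 3.

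**Figure D3:**
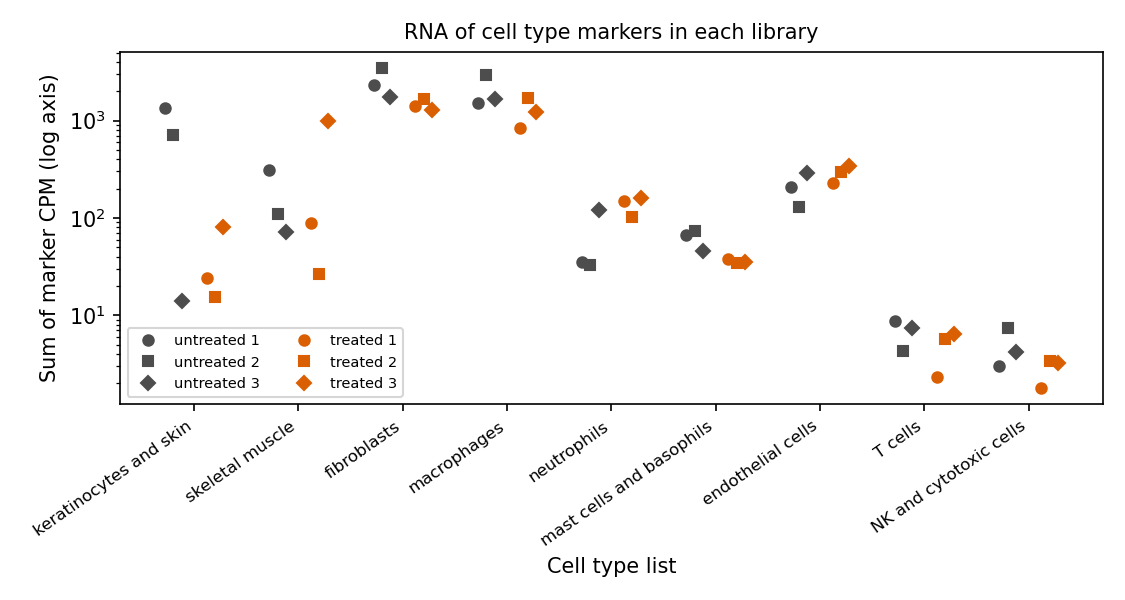
Sum of CPM over the markers of 9 cell type lists (vertical, log axis) in each untreated (grey) and treated (orange) library. Keratinocyte markers reach 1360 and 719 CPM in untreated 1 and 2 and stay at or below 79.8 CPM in the other 4 libraries, and muscle markers reach 1000 CPM in treated 3.

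Multidrug resistance genes, the theme of the series title, did not pass as a list (adjusted p 0.296, with 7 of 12 tested members higher, 0 over all genes and 0 adjusted over the list alone). *Abcb1a* and *Abcb1b*, the mouse genes for the drug efflux pump P-glycoprotein (chromosome 5, 8660077 to 8748575 and 8798147 to 8866315), had 3.07 ± 0.257 CPM against 2.14 ± 0.749 and 45.2 ± 7.12 against 33.8 ± 4.08 (SD, n = 3). The log2 fold changes were 0.49 ± 0.39 and 0.42 ± 0.21 (SE). They are close paralogues, so their counts are uncertain where reads fit both. *Abcc1*, a further efflux pump (chromosome 16, 14361558 to 14475737), had 250.6 ± 33.1 CPM against 174.9 ± 27.1, a log2 fold change of 0.52 ± 0.22, and *Abcc4* had 46.6 ± 7.72 against 19.5 ± 12.8. *Abcg2* (13.8 ± 1.72 against 18.8 ± 6.39 CPM) and *Abcc3* (19.1 ± 5.38 against 24.3 ± 1.77 CPM) lay in the other direction. None passed edgeR's test, with adjusted p of 0.592 or more.

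**Figure D4:**
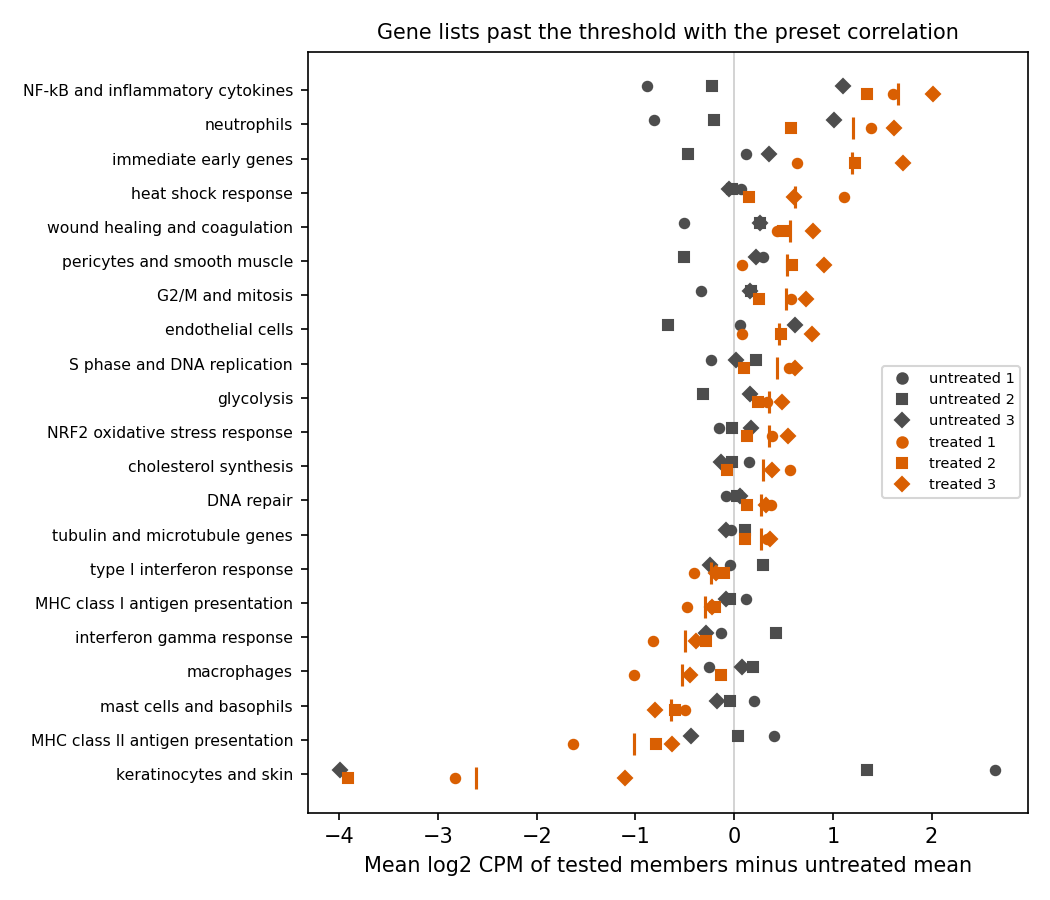
Mean log2 CPM of the tested members of the 21 lists past the threshold with the preset correlation, minus the untreated mean (horizontal), for each untreated (grey) and treated (orange) library. Vertical orange bars are treated means, from 1.66 for NF-kB and inflammatory cytokines, where untreated 3 lies at 1.10, to -2.62 for keratinocytes and skin.

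The remaining lists did not pass with the preset correlation. The adjusted p was 0.0565 for matrix metalloproteinases and inhibitors, where *Mmp13* passed adjusted over the list alone and was called by DESeq2 (0.000715), and 0.112 for the TGF-beta and mesenchymal list, where 2 members did, *Cyr61* (DESeq2 adjusted p 2.49e-08) among them. *Lum*, in the collagen and fibroblast lists and named after its values were seen, was called lower by DESeq2 (0.0499). It was 0.146 for the unfolded protein response, 0.213 for lysosome and autophagy, 0.228 for collagens and matrix, 0.232 for dendritic cells, 0.264 for apoptosis regulators, 0.27 for fibroblasts and 0.296 for Schwann cells. It was 0.356 for erythroid cells, 0.384 for Wnt targets and for alternatively activated macrophages, 0.385 for ribosomal proteins, 0.391 for oxidative phosphorylation and 0.8 for complement. Some of these lists passed with the preset correlation when 1 library was left out, fits in which no estimated correlation was run. Without untreated 2 the unfolded protein response (0.38, adjusted p 0.00259), oxidative phosphorylation (0.20, 0.00259) and ribosomal proteins (0.20, 0.00174) rose. The metalloproteinase list rose without untreated 3 (0.72, 0.0301) and without treated 3 (0.53, 0.0238), the TGF-beta list without treated 3 (0.36, 0.0249) and erythroid markers without treated 2 (0.77, 0.03). Dendritic cell markers fell without untreated 3 (-0.8, 0.0258), treated 2 (-0.8, 0.00446) or treated 3 (-0.61, 0.0246). The complement list had a positive median and mean fold change and a test direction below 0, and its 3 C1q genes passed adjusted over the list alone. Markers of T cells and of NK cells summed to 2.32 to 8.77 and 1.79 to 7.36 CPM per library, and those of B cells to 1.12 to 4.99 CPM. These lists, with plasma cells, adipocytes and hair follicle, had fewer than 5 members past the filter and were tested only with no filter. There NK cell markers (-0.33, adjusted p 0.0383) and adipocyte markers (-0.52, 0.00623) fell, and T cell, B cell, plasma cell and hair follicle markers did not pass (0.291, 0.845, 0.845 and 0.434). Dendritic cell markers (-0.55, 0.00668) and the metalloproteinase list (0.53, 0.0383) also passed with no filter, and no estimated correlation was run there. Mitochondrially encoded genes were not among the symbols of the tables used here.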

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

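The GC and length correction, the quality weights, the DESeq2 fit on 5 libraries and fry were chosen after the data were seen, and the other alternatives before. Genes higher and lower were 0 and 0 with DESeq2 size factors, the upper quartile, limma-voom, no filter, the stricter filter and the GC and length correction. They were 15 and 30 with DESeq2, 1 and 1 with quality weights (*Cyr61* and *Txnip*, untreated 2 being weighted 0.0791 and the others at least 1.18), and 105 and 127 with DESeq2 on the 5 libraries other than untreated 2. The 45 DESeq2 calls with all libraries and the 232 without untreated 2 shared 20 genes. Leaving out each library in turn gave 0 to 0 genes higher and 0 to 4 lower, the 4 without untreated 3, at unadjusted counts of 313 (without treated 3) to 2362 (without untreated 2). Why DESeq2 called genes where edgeR did not was not tested.

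Lists higher and lower were 14 and 7, the same with DESeq2 size factors, 14 and 6 with the upper quartile, 15 and 10 with no filter, 11 and 6 with the stricter filter, 10 and 6 with the GC and length correction, 15 and 5 with quality weights, 0 and 0 with an estimated correlation, and 0 and 0 with fry, which tests each list against no change and not against other genes, and whose smallest adjusted p was 0.313. Leaving out each library in turn gave 6 to 15 lists higher and 3 to 9 lower. Both lowest counts, 6 and 3, came without untreated 1, and 4 lists were lower without untreated 2. The lists for immediate early genes, inflammatory cytokines, G2 and M phases, neutrophils, macrophages and MHC class II passed in all 6 of these fits, at highest adjusted p of 2.01e-05, 1.2e-05, 0.0202, 0.0115, 0.0318 and 0.00419. Of the 21 calls, the GC and length correction lost tubulin, glycolysis, type I interferon, endothelial cells and pericytes, the stricter filter tubulin, type I interferon, wound healing and pericytes, quality weights type I interferon, endothelial cells, pericytes and keratinocytes, and the upper quartile type I interferon. No called list changed direction under any alternative, and 90 of 315 comparisons of a called list with an alternative lost the call. The estimated correlation and fry, both run on all 6 libraries, each kept 0 of the 21 calls. Fits without 1 library kept 9 (without untreated 1) to 20 (without treated 2) of them at the same number of samples. Fewer samples therefore do not account for the losses with the estimated correlation and fry. For the fits without 1 library the comparison cannot decide, since each leaves out a different library. The cause of the losses was not tested further. Among the other lists tested with the filter, 17 comparisons gained a call with the direction kept, and NK cell and adipocyte markers, tested only with no filter, were called lower there. At 4680295 to 8019294 counts per library, genes under the filter could not be tested. A pseudocount of 0.1 and limma without a trend, meant for normalised values, were not run.

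The replicate numbers gave no sign of pairing the samples. The correlation of deviations from the group means was -0.182, -0.11 and 0.108 for same-numbered samples, and for no number was it the highest. With the number as a block, 0 genes were called, and 14 lists were higher and 7 lower, 20 of them shared with the unblocked test. The block lost the call of the tubulin list and gained that of the metalloproteinase list.

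Some results short of the threshold changed sign, and skeletal muscle also passed it that way without treated 2 (1.02, adjusted p 0.0359). The cause was not tested. For lists the direction is that of the test against other genes, and the value a mean log2 difference. With quality weights, the collagen list was at 0.05, muscle at 0.05, Schwann cells at 0.02, *Dnaja1* at 0.02, *Jund* at 0.17, *Cdk1* at 0.52, *Ccne2* at 0.15, *Slbp* at 0.23, *Krt14* at 0.33 and *Acta1* at -0.32. With DESeq2 on 5 libraries *Dnaja1* was at 0.05, *Jund* at 0.17, *Cdk1* at 0.53, *Ccne2* at 0.18 and *Slbp* at 0.23. *Cdk1* was at 0.10 with limma-voom and 0.11 with the block, *Acta1* at -0.83 with each, *Slbp* at 0.10 with the GC correction, and angiogenic factors at -0.03 with the stricter filter. Leaving out each library gave ranges of -0.01 to 0.20 for oxidative phosphorylation, -0.08 to 0.20 for ribosomal proteins, 0.03 to 0.65 for collagens, -0.16 to 0.54 for complement, -0.28 to 0.34 for alternatively activated macrophages, -0.35 to -0.01 for fibroblasts, -1.5 to 1.02 for skeletal muscle and 0.01 to 0.55 for Schwann cells. The ranges were -0.63 to 0.04 for *Dnaja1*, -0.22 to 0.17 for *Jund*, -0.29 to 0.52 for *Cdk1*, -1.13 to 0.18 for *Ccne2*, -0.22 to 0.22 for *Slbp*, -0.01 to 0.38 for *H2-T23*, -0.03 to 0.57 for *Cd14* and -1.78 to 2.78 for *Acta1*.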

Other observations

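The tests of splits and of thinned counts were set before their results were seen, and the other tests below after. Among DESeq2's 45 calls were the genes below, chosen after their values were seen and not tested as groups. Of these, *Lum*, *Dmkn*, *Hrnr* and *Klk7* were also named above. *Fcrls* and *Gpr34*, receptors known from tissue macrophages and microglia, had log2 fold changes of -2.69 ± 0.53 and -2.93 ± 0.66 (SE, DESeq2 adjusted p 0.000843 and 0.00841). *Enpp2*, which makes lysophosphatidic acid, had -3.03 ± 0.62 (0.00143), and *Rgs16*, which dampens G protein signals, 2.37 ± 0.44 (0.000218). *Mcpt2* and *Tpsab1*, mast cell proteases, had -3.02 ± 0.75 (0.0307) and -2.45 ± 0.61 (0.0318), and *Kera* and *Lum*, proteoglycans of connective tissue, -3.36 ± 0.77 (0.0109) and -2.70 ± 0.71 (0.0499). *Lum* had 432, 1320 and 160 CPM in untreated 1, 2 and 3 and 48 to 130 CPM in treated tumours. *Dmkn*, *Hrnr* and *Klk7*, known from epidermis, had -5.04 ± 1.14 (0.00897), -7.47 ± 1.71 (0.0109) and -7.05 ± 1.71 (0.022). Keratinocyte marker RNA was high in untreated 1 and 2, so skin may contribute to these 3 calls. With all libraries edgeR called none of the genes named here, and *Hrnr* and *Klk7* did not pass its filter. Of the 45 genes 20 were among the 232 that DESeq2 called without untreated 2.

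The closest pair of libraries crossed the groups. Untreated 3 and treated 2 had a Spearman correlation over genes of 0.9905 and a chi-square per gene of 5.64, against 0.980 to 0.9817 and 11.7 to 15.6 within the treated group. No explanation was tested for this.

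Splitting the 6 libraries into 3 and 3 in all 10 ways gave 0 called genes in each of the 10 splits, with 0 in the real one and 0 as the highest other. The real split had the most genes at an unadjusted p under 0.05 (1 of 10 splits reached 1023, the highest other being 974) and the most called lists (1 of 10 splits reached 21, the highest other being 15). With 10 splits no share under 0.05 is possible. Each split other than the real one also called lists with the preset correlation, from 3 to 15. A small adjusted p from that version therefore does not by itself mark an effect of treatment.

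Untreated 2 stood apart from the other libraries. Fewer counts do not account for this, since with all libraries thinned to its total of 4680295 its mean distance was 1.19 and the largest of the others 0.698. Skin tissue alone does not either, since untreated 1 held more keratinocyte RNA and had a mean distance of 0.729 against 1.22. GC content and transcript length accounted for 0.419 of the variance over genes of its deviations and at most 0.181 in the others, so a difference in RNA quality or library preparation may be part of the gap, but with that trend removed its mean distance was still 0.937 against at most 0.661. What makes up the rest stays open, a difference in the tumour itself included.

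Inflammatory genes were higher in treated tumours. The trend with GC content and length is not the whole cause, as the mean difference was 1.71 with it removed (adjusted p 2.37e-09 with the preset correlation). Without that correction the list had an adjusted p of 0.499 with an estimated correlation and fry, which tests a list against no change, called none (smallest adjusted p 0.313). Differences between untreated tumours cannot be told apart from an effect of treatment, because the lowest treated library lay only 0.25 above untreated 3 while the untreated SD was 1.00, and neutrophil markers, at 1.2 in treated tumours, lay at 1.01 in untreated 3. Keratinocyte list values ran the other way in untreated 1, 2 and 3 (2.64, 1.35 and -3.99, against -0.88, -0.22 and 1.10 for the inflammatory list). Among treated tumours both lists were highest in treated 3 (-1.11 and 2.01). Skin in untreated 1 and 2 was not tested as an explanation here and cannot be told apart from treatment. A hypothesis is that treatment raises an inflammatory programme that may also arise in untreated tumours, as in untreated 3, and more tumours per group would be needed to test it.

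The macrophage, MHC class II and mast cell lists were lower in treated tumours, and the GC and length trend is not the whole cause, as with it removed the differences were -0.58, -1.09 and -0.66 (adjusted p 0.00376, 0.000144 and 0.01 with the preset correlation). Without that correction each had an adjusted p of 0.499 with an estimated correlation. Skin in untreated 1 and 2 may contribute, since both mast cells and MHC class II cells are found in skin. Untreated 3, which had little keratinocyte RNA, lay 0.61, 0.58 and 0.46 above the treated mean in these lists. It lay closer to the nearest treated library, at 0.08 against -0.13 in treated 2 for macrophages. For MHC class II it lay at -0.44 against -0.63 in treated 3, and for mast cells at -0.17 against -0.5 in treated 1. The treated SD was 0.45, 0.54 and 0.15. Untreated 1, with the most keratinocyte RNA, had the lowest untreated macrophage value (-0.26, against 0.19 and 0.08 in untreated 2 and 3), which runs against skin for that list, while MHC class II (0.40, 0.04 and -0.44) and mast cells (0.20, -0.04 and -0.17) were highest in untreated 1. As each of these rests on single libraries, skin and treatment cannot be told apart here.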
